A study of Homo sapiens with 6 samples.

How the data were processed

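The series holds 6 RNA-seq libraries of human NK cells, 3 in which FLI1 was knocked out with CRISPR and 3 of a control labelled NTC. Per the labels' protocols, total RNA was extracted with a column kit, 10 ng was used per library, and libraries were made with the Illumina RNA Prep with Enrichment kit. The probe panel of the enrichment, the guide sequence, the origin and culture of the cells and the meaning of the replicate numbers are not given in the sources used here. The authors deposited raw counts per Ensembl gene for 60676 gene IDs, with a column of whole numbers per library and no normalisation. Per the submitters' processing notes, reads were checked with FastQC 0.12.0, trimmed with Trimmomatic 0.39 and aligned with STAR 2.7.11 to hg38. The counting program, the annotation release and the strand setting are not given in the sources used here, so reads of overlapping, antisense or near-identical genes could not be told apart.

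Gene symbols were taken from a table of gene names, which matched 60357 of the IDs. Gene type, position, coding length and GC content came from GENCODE 29 on GRCh38, which holds 58503 of the IDs. A set of 511 genes was left out of every step, and 60165 were kept. Total counts ran from 22300000 to 48100000 per library, to 3 significant digits. No pair of libraries of a group was a duplicate, since their chi-square per degree of freedom ran from 19.8 to 41.7. Levels are CPM, counts divided by the TMM-scaled library size in the usual unit of edgeR, with SD over 3 libraries.

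Genes were tested in R 4.3.3 with the quasi-likelihood test of edgeR 4.0.16 after filterByExpr with a minimum count of 10 and TMM normalisation, which kept 19704 genes. The unpaired fit held the group as its only term, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. The labels name no donor, but the libraries of FLI1 KO and NTC that share a replicate number resembled each other. The correlation of their log2 CPM, centred within each group, was 0.523, 0.653 and 0.548 for replicates 1, 2 and 3, and the highest with another number was -0.183, -0.254 and -0.183. Centring within groups of 3 itself pushes the latter to negative values. Without centring, the chi-square per degree of freedom was 11.8, 7.84 and 4.42 between FLI1 KO and NTC libraries of the same number. Between those of different numbers the lowest was 22.3. A paired fit with replicate number as a block, planned as an alternative, is therefore given beside the unpaired one. The difference is FLI1 KO minus NTC throughout, and "rose" and "fell" refer to the paired edgeR fit over all tested genes unless another fit is named.

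The 36 gene lists and 6 lists of markers of other cell types were tested with camera of limma 3.58.1 with a preset inter-gene correlation of 0.01, two-sided, adjusted over all lists. Camera with an estimated correlation and fry, whose directional p does not compare a list with other genes, were run as alternatives. Log2 CPM used a prior count of 2. The groups, the unpaired tests, the lists, the first set of alternatives and the rule for named genes were fixed before the data were examined. The rule took FLI1, then the 10 largest rises and falls past the threshold at 5 CPM or more, or the 5 of smallest unadjusted p per direction if fewer than 5 passed. From each gene list it took the members of smallest unpaired p, up to 4 if the list or a member passed and 2 otherwise. Members named from a gene list are therefore its extremes in these data, not typical members. From each marker list it took up to 4 of the most abundant members. As no gene passed the unpaired edgeR test, a further rule was added after seeing the data. It took the 10 largest rises and falls in the paired fit at 5 CPM or more that went the same way in all 3 pairs. HLA and KIR genes, receptor gene segments, antisense genes, pseudogenes, genes with symbols of the form used for pseudogenes and genes without a symbol were not named, and 1 gene taken by the rule is not reported here.

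Alternatives fixed in advance were DESeq2 size factors inside edgeR, no filter on low counts, a stricter filter (at least 1 CPM in 3 libraries and 10 counts), the Wald test of DESeq2 1.42.0, limma-voom with sample quality weights, the replicate block, a limit of 1.5-fold and leaving out each library. Chosen after seeing the data were protein-coding genes only, genes with a mean of at least 5 CPM normalised and fitted alone, each alternative in the paired fit, leaving out each replicate pair, and the removal of a trend with coding length and GC content per library (loess span 0.3). The families silent in lymphocytes were listed before their counts were read.

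The fits were tested on simulated counts of the same 19704 genes and 6 libraries with 200 changed genes, all with a mean of at least 5 CPM. Counts were drawn from the paired model, with its replicate effects and its spread, so the simulation favours the paired fit. The unpaired edgeR fit recovered 0%, 26%, 68% and 98% of genes changed by 1.25-fold, 1.5-fold, 2-fold and 4-fold, and 0% of its calls were false. The paired fit recovered 72%, 98%, 100% and 100%, and 6.57% of its 198 calls were false. With the proteasome subunits raised by 1.25-fold, preset camera found that list in both fits and called 0 of 41 other lists. Counts were drawn independently for each gene, so this does not show how often preset camera calls unchanged lists whose genes vary together. With an estimated correlation that raised list had an adjusted p of 0.165 in the unpaired fit and 0.0377 in the paired fit, and with fry 0.72 and 0.0735.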

Results

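RNA was sequenced from human natural killer (NK) cells in which CRISPR had been used to knock out FLI1, a transcription factor of the ETS family, and from NK cells of a control labelled NTC. Each group held 3 libraries, numbered as replicates 1 to 3. To 3 significant digits, the total counts of the FLI1 KO libraries were 39500000, 48100000 and 29600000 for replicates 1, 2 and 3, and those of the NTC libraries 35100000, 40900000 and 22300000. At these depths 19704 genes had enough counts to be tested. The series title places FLI1 in the control of protein homeostasis under nutrient shortage, and the comparison asks which transcripts differed between NK cells with and without the knockout. The labels of these 6 libraries name no nutrient condition and no tumour. They also do not say whether the replicates were separate donors or cultures, so the p-values measure only the spread between these libraries.

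FLI1 (ENSG00000151702) spans positions 128686535 to 128813267 on the plus strand of chromosome 11 in the GRCh38 build, and its coding length is 1356 bases. FLI1 transcripts were present in all FLI1 KO libraries, at 139 ± 2.82 CPM in FLI1 KO and 151 ± 8.06 CPM in NTC (mean ± SD, n = 3). The raw counts were 5382, 6937 and 3944 in FLI1 KO replicates 1, 2 and 3 and 4962, 6536 and 3435 in NTC replicates 1, 2 and 3. The log2 difference, FLI1 KO minus NTC, was -0.12 (SE 0.064) and did not pass the edgeR test, whose adjusted p rounds to 1. With libraries paired by replicate number it was -0.12 (SE 0.042, edgeR adjusted p = 0.187), lower in all 3 pairs and not past the threshold. Counts per gene do not show the edited site, and a short insertion or deletion need not lower the RNA, so these values do not check the labels.

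The change in the transcriptome of NK cells was small, and with the filter used no gene passed the unpaired edgeR test. Among 10765 genes with a mean of at least 5 CPM (counts scaled to library size), 149 rose and 69 fell in the paired edgeR fit, and the SD of their log2 differences was 0.12. The genes that rose had a median fold change of 1.18 and those that fell 0.786, and 18 of these calls reached 1.5-fold. CXCL8, which encodes a chemokine that attracts neutrophils, rose by 1.10 (SE 0.18, edgeR adjusted p = 0.00386), with 8.95 ± 7.68 CPM in FLI1 KO and 4.01 ± 3.55 CPM in NTC (SD, n = 3). In replicate 2 its level was only 0.68 CPM in FLI1 KO and 0.63 CPM in NTC. IFNG, the main cytokine released by activated NK cells, rose by 0.38 (SE 0.052, edgeR adjusted p = 0.00125), with 231 ± 61.5 CPM in FLI1 KO and 177 ± 41.9 CPM in NTC. The adhesion ligand gene ICAM1 rose by 0.36 (SE 0.051, edgeR adjusted p = 0.00159), and CORO1A, which encodes a regulator of actin filaments, rose by 0.38 (SE 0.063, edgeR adjusted p = 0.00553). The histone gene H3C10 rose by 0.65 (SE 0.099, edgeR adjusted p = 0.00289) and the ribosomal protein gene RPL10 by 0.40 (SE 0.046, edgeR adjusted p = 0.000202). COX8A, which encodes a subunit of cytochrome c oxidase, had the largest fall among the named genes of at least 5 CPM and fell by 1.05 on the log2 scale (SE 0.092, edgeR adjusted p = 1.86e-05), with 12.6 ± 3.01 CPM in FLI1 KO and 25.6 ± 4.08 CPM in NTC. IL2RG, the receptor chain shared by interleukins 2 and 15, fell by 0.44 on the log2 scale (SE 0.051, edgeR adjusted p = 0.000202), with 277 ± 19.4 CPM in FLI1 KO and 376 ± 42.5 CPM in NTC. ZNF683, a transcription factor gene of tissue-resident lymphocytes, changed by -0.50 (SE 0.10, edgeR adjusted p = 0.0204) and S100A4, which encodes a calcium-binding protein, by -0.50 (SE 0.089, edgeR adjusted p = 0.00920). In the unpaired fit ZNF683 had a log2 fold change of 0.024 without FLI1 KO replicate 2 and 0.14 without NTC replicate 3. Leaving out a single library unbalances the replicate numbers between the groups, and the ZNF683 differences in pairs 1, 2 and 3 were -0.68, -0.55 and -0.31.

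**Figure D1:**
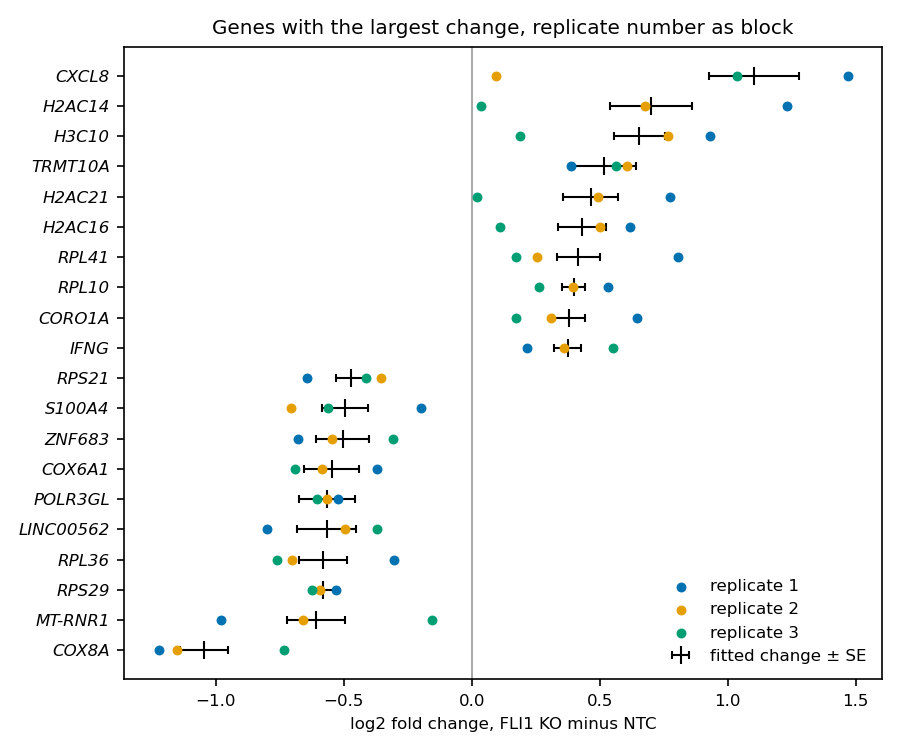
Log2 fold change, FLI1 KO minus NTC, of the 10 genes with the largest rise and the 10 with the largest fall at 5 CPM or more in the paired edgeR fit, pseudogenes and other genes not named here left out (black ticks with SE), and the difference in each replicate pair (coloured points). All 20 genes went the same way in all 3 pairs because the rule took only such genes, and COX8A and CXCL8 changed most among them. The difference of CXCL8 in pair 2 was 0.096.

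Further named genes with large differences included histone, ribosomal protein and respiratory chain genes. Pseudogenes are not named here, and 13 of those with at least 5 CPM fell and 2 rose. The median absolute log2 difference of these calls was 0.85 and the largest 2.31. H2AC14 rose by 0.70 on the log2 scale, H2AC21 by 0.46 and H2AC16 by 0.43, with edgeR adjusted p of 0.0358, 0.0361 and 0.0270 in the paired fit. Unpaired and without FLI1 KO replicate 1, which unbalances the replicate numbers, the log2 fold change was -0.030 for H2AC21 and -0.066 for H2AC16. TRMT10A, which encodes a tRNA methyltransferase, rose by 0.52 (SE 0.12, edgeR adjusted p = 0.0434) and the ribosomal protein gene RPL41 by 0.42 (SE 0.084, edgeR adjusted p = 0.0188). The ribosomal protein genes RPS29, RPL36 and RPS21 fell by 0.58, 0.58 and 0.47 on the log2 scale, with edgeR adjusted p of 8.92e-06, 0.00463 and 0.000331. COX6A1, another cytochrome c oxidase subunit gene, changed by -0.55 (edgeR adjusted p = 0.0141), POLR3GL, an RNA polymerase III subunit gene, by -0.57 (edgeR adjusted p = 0.0158), the long noncoding RNA LINC00562 by -0.57 (edgeR adjusted p = 0.0193) and MT-RNR1, the small mitochondrial ribosomal RNA, by -0.61 (edgeR adjusted p = 0.0123). Lower calls were most frequent among short coding sequences. Of 154 genes with a coding length under 300 bases, 9 fell and 3 rose, and of 2225 genes of at least 2400 bases, 2 fell and 44 rose. Of 980 genes from 300 to under 600 bases, 16 fell and more, 23, rose. Reads of RPL10, RPL41, RPS29, RPL36, RPS21 and the histone genes are uncertain because these genes have near-identical copies or processed pseudogenes. Of 91 named genes, 60 overlap another annotated gene, 44 of them on the other strand, and the strand setting of the counting is not given in the sources used here.

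These calls rested on the pairing and, for the rises, on the set of genes fitted. Without pairing, the edgeR test called 0 of 19704 genes, although 713 had an unadjusted p under 0.05. It called 246 genes with no filter on low counts (23 higher, 223 lower) and 1 with a stricter filter. DESeq2 called 64 genes, all lower, and limma-voom 0. In the unpaired comparison 1832 genes (9.30%) had groups that did not overlap, where chance gives 10% for libraries that are all unrelated. Libraries that shared a replicate number resembled each other, so 10% is not the share to expect without a change, and this comparison does not decide. Paired over all tested genes, edgeR called 149 higher and 250 lower. No gene under 5 CPM rose, while 99 protein-coding genes and 69 pseudogenes of that level fell. When the genes of at least 5 CPM were normalised and fitted alone, 21 rose and 68 fell, including 21 and 61 of the calls above. Their median log2 difference went from 0.032 to 0.0019, a move of 0.030 that took away nearly all of it. CXCL8, IFNG, ICAM1, CORO1A, H3C10 and RPL10 passed in both fits, with edgeR adjusted p of 0.0168, 0.00902, 0.00959, 0.0342, 0.0244 and 0.00360 in the restricted fit. All 10 genes named for the largest falls passed in both, with edgeR adjusted p from 7.69e-05 to 0.0359 in the restricted fit, for RPS29 and ZNF683. H2AC14, H2AC21, H2AC16, TRMT10A and RPL41 did not pass there, with edgeR adjusted p of 0.106, 0.112, 0.0898, 0.0862 and 0.0742. Leaving out replicate pair 2 left 57 calls, 3 of them higher, and leaving out pair 3 gave 867.

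The named genes with the smallest unadjusted p in the unpaired edgeR test did not pass it. Neither did the genes left unnamed, mostly pseudogenes, whose smallest adjusted p was 0.0631. The 5 higher named genes were RPL10, IRF1, SLFN11, ICAM3 and the microRNA gene MIR5587, with unpaired log2 differences of 0.40, 0.19, 0.21, 0.30 and 1.21. IRF1, a transcription factor gene of the interferon response, rose by 0.19 (SE 0.040, edgeR adjusted p = 0.0244) with pairing, SLFN11 by 0.20 (SE 0.042, edgeR adjusted p = 0.0209) and the adhesion receptor gene ICAM3 by 0.30 (SE 0.057, edgeR adjusted p = 0.0136). With the genes of at least 5 CPM fitted alone these 3 had edgeR adjusted p of 0.0693, 0.0579 and 0.0507. MIR5587 had 124 counts in FLI1 KO and 44 in NTC, summed over libraries, and lies within CAPN15, whose reads it can share. Its paired edgeR adjusted p was 0.114. The 5 lower named genes were RPS29 and 4 genes of very low counts. PTH1R had 3 counts in FLI1 KO and 81 in NTC, ALK 2 and 40, PPP1R3G 2 and 35 and C5orf64 2 and 32, and their paired edgeR adjusted p were 0.00126, 0.0136, 0.0206 and 0.0262.

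Gene lists fixed from knowledge of NK cells and of the series title moved by small amounts. Sterol and fatty acid synthesis, glycolysis and the unfolded protein response were higher in FLI1 KO, and oxidative phosphorylation and mitochondrially encoded transcripts were lower. These 5 lists passed the paired camera test over genes of at least 5 CPM with all libraries and with any replicate pair left out. With an estimated correlation each had an adjusted p = 0.643 there, as had every other list that passed. Preset camera called 15 gene lists higher and 2 lower in that test, and 10 higher and 2 lower unpaired at 5 CPM. Unpaired and over all tested genes, 18 gene lists were higher and 3 lists lower, the mitochondrially encoded transcripts and 2 lists of cell type markers. No list passed with an estimated correlation in either setting. No list passed fry, a test of whether members move one way on balance. Camera compares a list with the other genes tested, and protein-coding genes under 5 CPM had a median log2 difference of -0.20 against 0.036 for those of at least 5 CPM. In the unpaired edgeR fit no member of any gene list passed over all genes or adjusted over the list alone. Without replicate pair 1 the higher lists numbered 5, the hypoxia response among them. The tests that leave out a pair share libraries and are not independent. With FLI1 KO and NTC swapped in replicate pair 1, 2 or 3, preset camera paired at 5 CPM called 3, 6 and 11 lists, against 17 unswapped. In pair 3 the mitochondrially encoded transcripts had a median of 0.047, on the higher side.

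**Figure D2:**
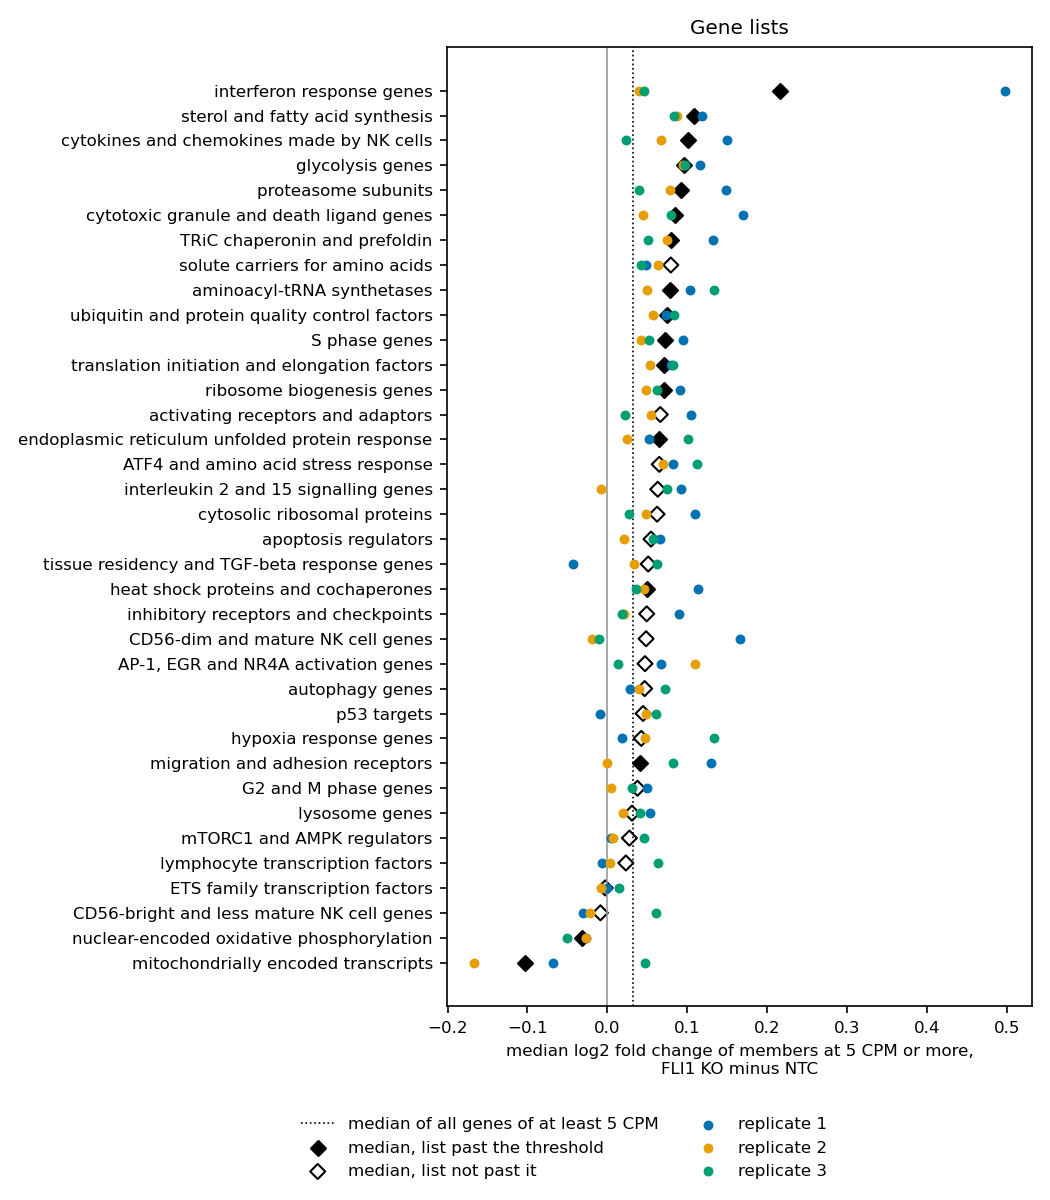
Median log2 fold change, FLI1 KO minus NTC, of the members of each gene list with a mean of at least 5 CPM (diamonds, filled where the paired camera test passed) and in each replicate pair (coloured points). Interferon response genes had the highest median, 0.22, and its value in pair 1 was 0.50.

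Lists of protein folding and degradation were mostly higher in FLI1 KO by the preset camera test, and none passed with an estimated correlation. The medians at 5 CPM or more were 0.050 to 0.092 on the log2 scale for the lists that passed, 0.047 for autophagy and 0.031 for lysosome genes, against 0.032 for all genes of that level. In the endoplasmic reticulum unfolded protein response list, 4 of 42 rose, 0 fell and 38 did not pass, with 7 higher and 0 lower adjusted over the list alone, and the camera adjusted p was 0.00969 paired and 0.00749 unpaired at 5 CPM and 0.000307 unpaired over all genes. DNAJB9, P4HB and PDIA4, which encode a cochaperone and protein disulfide isomerases of that compartment, rose by 0.27, 0.21 and 0.17 on the log2 scale (paired edgeR adjusted p = 0.0243, 0.0442 and 0.0493). Of proteasome subunits, 3 of 43 rose, 0 fell and 40 did not pass, with 11 higher and 0 lower adjusted over the list alone (camera adjusted p = 0.00124 paired and 0.000752 unpaired at 5 CPM, 7.38e-05 unpaired over all genes). PSMA3 rose by 0.23 (SE 0.049, edgeR adjusted p = 0.0245), PSMA5 by 0.22 (SE 0.049, edgeR adjusted p = 0.0296) and the ubiquitin receptor gene ADRM1 by 0.31 (SE 0.073, edgeR adjusted p = 0.0431). Of the cytosolic chaperonin TRiC and prefoldin, 2 of 14 rose, 0 fell and 12 did not pass, with 4 higher and 0 lower adjusted over the list alone (camera adjusted p = 0.0377 paired and 0.0962 unpaired at 5 CPM, 0.0123 unpaired over all genes). CCT5 rose by 0.23 (SE 0.046, edgeR adjusted p = 0.0160) and CCT6A had a difference of 0.15 (edgeR adjusted p = 0.0804). Of heat shock proteins and cochaperones, 2 of 43 rose, 0 fell and 41 did not pass, with 11 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.0290 paired and 0.0501 unpaired at 5 CPM, 0.00480 unpaired over all genes). HSF1, the transcription factor that drives heat shock genes, rose by 0.25 (SE 0.059, edgeR adjusted p = 0.0434), while AHSA1 and HSPE1 had differences of 0.26 (edgeR adjusted p = 0.0577) and -0.34 (edgeR adjusted p = 0.0743). Of ubiquitin and protein quality control factors, 2 of 31 rose, 1 fell and 28 did not pass, with 5 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.0426 paired and 0.0796 unpaired at 5 CPM, 0.00326 unpaired over all genes).

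VCP, the ATPase that extracts ubiquitinated proteins, rose by 0.23 (SE 0.043, edgeR adjusted p = 0.0112), and NFE2L1, which drives proteasome genes, by 0.20 (SE 0.044, edgeR adjusted p = 0.0301), while the ubiquitin receptor gene UBQLN2 changed by -0.22 (SE 0.048, edgeR adjusted p = 0.0296). Of aminoacyl-tRNA synthetases, 1 of 23 rose, 0 fell and 22 did not pass, with 7 higher and 0 lower adjusted over the list alone (camera adjusted p = 0.00608 paired and 0.00639 unpaired at 5 CPM, 0.000742 unpaired over all genes). WARS1 rose by 0.19 (SE 0.042, edgeR adjusted p = 0.0281) and AARS1 had a difference of 0.15 (edgeR adjusted p = 0.0943). Autophagy genes did not pass (camera adjusted p = 0.740 paired and 0.760 unpaired at 5 CPM, 0.238 unpaired over all genes), and 0 of 45 rose, 0 fell and 45 did not pass, with 0 higher and 0 lower adjusted over the list alone. Their median over all tested members was 0.034 and their mean -0.047, of opposite sign. Lysosome genes did not pass (camera adjusted p = 0.824 paired and 0.785 unpaired at 5 CPM, 0.0728 unpaired over all genes), and 0 of 43 rose, 0 fell and 43 did not pass, with 3 higher and 1 lower adjusted over the list alone. NBR1 and ATP6AP1 had differences of 0.16 (edgeR adjusted p = 0.0786) and 0.21 (edgeR adjusted p = 0.0610). Each list of folding, degradation and tRNA charging that passed had an adjusted p = 0.643 with an estimated correlation in the paired test at 5 CPM. Without replicate pair 1 the camera adjusted p at 5 CPM were 0.0865 for proteasome subunits, 0.210 for TRiC and prefoldin, 0.229 for heat shock proteins and 0.0865 for ubiquitin factors. Without pair 2 they were 0.0895 for TRiC and prefoldin and 0.0895 for ubiquitin factors, and without pair 3 0.0751 for ubiquitin factors and 0.0663 for the synthetases. When the genes of at least 5 CPM were fitted alone, UBQLN2 passed (edgeR adjusted p = 0.0273) and the named genes that rose in these lists had edgeR adjusted p from 0.0507 for VCP to 0.130 for PDIA4.

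Lists of lipid synthesis and glycolysis genes were higher in FLI1 KO and lists of respiratory chain genes lower by the preset camera test in the paired fit at 5 CPM. With an estimated correlation there all 4 lists had an adjusted p = 0.643. The median fold change at 5 CPM or more was 1.08 for sterol and fatty acid synthesis, 1.07 for glycolysis, 0.978 for nuclear-encoded oxidative phosphorylation and 0.931 for mitochondrially encoded transcripts. Of sterol and fatty acid synthesis genes, 2 of 35 rose, 0 fell and 33 did not pass, with 8 higher and 0 lower adjusted over the list alone (camera adjusted p = 0.000207 paired and 0.000761 unpaired at 5 CPM, 0.000307 unpaired over all genes). FASN, the fatty acid synthase gene, rose by 0.21 (SE 0.039, edgeR adjusted p = 0.0107). Of glycolysis genes, 4 of 24 rose, 0 fell and 20 did not pass, with 9 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.00124 paired and 0.0200 unpaired at 5 CPM, 0.00326 unpaired over all genes). HK1, PFKL and the lactate exporter gene SLC16A3 rose by 0.23, 0.23 and 0.37 on the log2 scale (paired edgeR adjusted p = 0.0209, 0.0354 and 0.0433), and LDHB had a difference of -0.41 (edgeR adjusted p = 0.118). Of nuclear-encoded oxidative phosphorylation genes, 0 of 71 rose, 4 fell and 67 did not pass, with 2 higher and 9 lower adjusted over the list alone. COX8A fell by 1.05, COX6A1 by 0.55 and ATP5PF, an ATP synthase subunit gene, by 0.41 on the log2 scale, the last with an edgeR adjusted p of 0.0123. Their coding lengths are 207, 327 and 357 bases, and falls were most frequent among short coding sequences in general. The camera adjusted p of that list was 0.000232 paired and 1.93e-05 unpaired at 5 CPM, and 0.211 unpaired over all genes, where it did not pass. Paired over all genes the camera adjusted p was 0.0489, barely past the threshold, and 0.382 with an estimated correlation. Of mitochondrially encoded transcripts, 0 of 13 rose, 2 fell and 11 did not pass, with 1 higher and 4 lower adjusted over the list alone (camera adjusted p = 3.64e-05 paired and 2.63e-06 unpaired at 5 CPM, 0.0200 unpaired over all genes). MT-ND2 and MT-ATP6 fell by 0.27 and 0.23 on the log2 scale (paired edgeR adjusted p = 0.00385 and 0.0326).

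The mitochondrially encoded transcripts differed between pairs, with medians of -0.068, -0.17 and 0.047 in pairs 1, 2 and 3. FASN, ATP5PF, MT-ND2 and MT-ATP6 also passed with the genes of at least 5 CPM fitted alone (edgeR adjusted p = 0.0340, 0.0244, 0.00937 and 0.0458). With the trend of coding length and GC content removed in the paired fit of protein-coding genes at 5 CPM, FASN went from 0.18 (SE 0.035, edgeR adjusted p = 0.0358) to 0.12 (SE 0.036, edgeR adjusted p = 0.128) and lost the call. MT-ATP6 went from -0.26 (SE 0.052, edgeR adjusted p = 0.0389) to -0.24 (SE 0.053, edgeR adjusted p = 0.0542) and lost it too. ATP5PF and MT-ND2 kept it (0.0282 and 0.0105). With the trend removed the higher calls of that fit went from 27 to 39 and the lower from 60 to 58. Of the named genes, RPL41, SLFN11, CCT5, EIF4H, DNAJB9 and CCL3 gained a call (edgeR adjusted p = 0.0342, 0.0377, 0.0420, 0.0319, 0.0462 and 0.0229). HK1, PFKL and SLC16A3 did not pass in the fit of genes of at least 5 CPM, with edgeR adjusted p of 0.0635, 0.0911 and 0.117. The ATF4 and amino acid stress response list passed in the unpaired test over all genes (camera adjusted p = 0.0200, adjusted p = 0.298 with an estimated correlation) and not at 5 CPM (0.138 unpaired, 0.0872 paired), and 0 of 35 rose, 0 fell and 35 did not pass, with 3 higher and 0 lower adjusted over the list alone. Its members SHMT2, SLC7A5 and SESN2 had differences of 0.14 (edgeR adjusted p = 0.101), 0.15 (edgeR adjusted p = 0.126) and 0.19 (edgeR adjusted p = 0.231). Solute carriers for amino acids did not pass (camera adjusted p = 0.271 paired and 0.247 unpaired at 5 CPM, 0.139 unpaired over all genes), and 0 of 22 rose, 0 fell and 22 did not pass, with 0 higher and 0 lower adjusted over the list alone. Their median was 0.058 and their mean -0.028 over all tested members, and the glutamine transporter gene SLC38A2 had a difference of 0.13 (edgeR adjusted p = 0.0795). Regulators of the nutrient-sensing kinases mTORC1 and AMPK did not pass (camera adjusted p = 0.706 paired and 0.785 unpaired at 5 CPM, 0.211 unpaired over all genes), and 0 of 45 rose, 0 fell and 45 did not pass, with 0 higher and 0 lower adjusted over the list alone. Hypoxia response genes did not pass with all libraries (camera adjusted p = 0.415 paired and 0.352 unpaired at 5 CPM, 0.0655 unpaired over all genes) and passed without pair 1 (0.0230), and 0 of 29 rose, 0 fell and 29 did not pass, with 0 higher and 0 lower adjusted over the list alone. INSIG2 had a difference of 0.17 (edgeR adjusted p = 0.233).

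Lists of translation factors and ribosome biogenesis were higher in FLI1 KO by the preset camera test, while ribosomal protein genes went both ways. In the paired test at 5 CPM these 2 lists had an adjusted p = 0.643 with an estimated correlation. Preset camera gave 0.0733 and 0.170 without replicate pair 1. Of translation initiation and elongation factors, 3 of 43 rose, 0 fell and 40 did not pass, with 11 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.00834 paired and 0.00812 unpaired at 5 CPM, 0.000265 unpaired over all genes). EEF2, which encodes the factor that moves the ribosome along the message, rose by 0.25 (SE 0.045, edgeR adjusted p = 0.0101) and the initiation factor gene EIF4H by 0.26 (SE 0.052, edgeR adjusted p = 0.0165). Of ribosome biogenesis genes, 1 of 46 rose, 0 fell and 45 did not pass, with 1 higher and 0 lower adjusted over the list alone (camera adjusted p = 0.0426 paired and 0.0341 unpaired at 5 CPM, 0.00326 unpaired over all genes). NOP14 rose by 0.30 (SE 0.062, edgeR adjusted p = 0.0206) and NOP58 had a difference of 0.15 (edgeR adjusted p = 0.0843). Of cytosolic ribosomal proteins, 8 of 76 rose, 6 fell and 62 did not pass, with 21 higher and 11 lower adjusted over the list alone. That list passed in the unpaired test over all genes (camera adjusted p = 0.0170, adjusted p = 0.755 with an estimated correlation) and not at 5 CPM (0.694 unpaired, 0.664 paired). RPL10 and RPL41 rose by 0.40 and 0.42 on the log2 scale, and RPS29 and RPL36 fell by 0.58 and 0.58. Without pair 2 the biogenesis list had 0.0971, and without pair 3 the ribosomal protein list passed (camera adjusted p = 0.00768). In the unpaired fit the median log2 fold change of the cytosolic ribosomal proteins was 0.066, and -0.014 without FLI1 KO replicate 1. EEF2, EIF4H and NOP14 had edgeR adjusted p of 0.0507, 0.0662 and 0.0659 with the genes of at least 5 CPM fitted alone.

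Lists of effector genes of NK cells were slightly higher in FLI1 KO by the preset camera test. In the paired test at 5 CPM the cytotoxic, cytokine and migration lists had an adjusted p = 0.643 with an estimated correlation. Preset camera gave 0.129, 0.116 and 0.210 without replicate pair 1. The median log2 difference at 5 CPM or more was 0.085 for cytotoxic granule and death ligand genes and 0.10 for cytokines and chemokines. Of the former, 2 of 21 rose, 0 fell and 19 did not pass, with 5 higher and 0 lower adjusted over the list alone (camera adjusted p = 0.00235 paired and 0.0239 unpaired at 5 CPM, 0.00332 unpaired over all genes). NKG7, which encodes a granule membrane protein, rose by 0.20 (SE 0.047, edgeR adjusted p = 0.0430) and GZMM, a granzyme gene, had a difference of 0.19 (edgeR adjusted p = 0.238). Of cytokines and chemokines made by NK cells, 3 of 21 rose, 0 fell and 18 did not pass, with 8 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.0204 paired and 0.228 unpaired at 5 CPM, 0.0281 unpaired over all genes), the risers being IFNG, CXCL8 and CCL3. CCL3 rose by 0.18 (SE 0.038, edgeR adjusted p = 0.0257), and its reads can be shared with its near-identical copies. Of activation genes of the AP-1, EGR and NR4A families, 3 of 32 rose, 0 fell and 29 did not pass, with 5 higher and 0 lower adjusted over the list alone, and the list passed unpaired over all genes (camera adjusted p = 0.0200, adjusted p = 0.339 with an estimated correlation) and not at 5 CPM (0.228 unpaired, 0.0745 paired, or 0.0456 paired without replicate pair 3). DUSP5, a phosphatase gene of that list, rose by 0.21 (SE 0.047, edgeR adjusted p = 0.0327) and BATF had a difference of 0.34 (edgeR adjusted p = 0.257). Of migration and adhesion receptors, 6 of 37 rose, 0 fell and 31 did not pass, with 7 higher and 0 lower adjusted over the list alone (camera adjusted p = 0.0132 paired and 0.0754 unpaired at 5 CPM, 0.0242 unpaired over all genes). Of its members, ICAM1 and ICAM3 rose by 0.36 and 0.30, and S1PR5, a receptor for the exit of NK cells from tissues, by 0.29 (SE 0.059, edgeR adjusted p = 0.0193).

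Without replicate pair 2 or 3 the cytotoxic, cytokine and migration lists passed preset camera at 5 CPM. NKG7, CCL3, DUSP5 and S1PR5 had edgeR adjusted p of 0.132, 0.0920, 0.0841 and 0.0702 with the genes of at least 5 CPM fitted alone, where they did not pass. Of activating receptors and adaptors, 0 of 29 rose, 1 fell and 28 did not pass, with 2 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.451 paired and 0.602 unpaired at 5 CPM, 0.0603 unpaired over all genes). With all libraries and the filter used on low counts, the list was called higher only when paired over all genes (camera adjusted p = 0.0103, and 0.382 with an estimated correlation). HCST, the adaptor of the activating receptor NKG2D, changed by -0.28 (SE 0.054, edgeR adjusted p = 0.0159) and passed in both fits (0.0173 in the restricted fit), and VAV1 had a difference of 0.15 (edgeR adjusted p = 0.143). Of inhibitory receptors and checkpoints, 1 of 21 rose, 0 fell and 20 did not pass, with 2 higher and 0 lower adjusted over the list alone (camera adjusted p = 0.614 paired and 0.628 unpaired at 5 CPM, 0.139 unpaired over all genes). INPP5D, a phosphatase gene, rose by 0.17 (SE 0.041, edgeR adjusted p = 0.0485) with an edgeR adjusted p of 0.128 in the restricted fit, and DGKA had a difference of 0.12 (edgeR adjusted p = 0.217). Of interleukin 2 and 15 signalling genes, 5 of 30 rose, 2 fell and 23 did not pass, with 5 higher and 2 lower adjusted over the list alone (camera adjusted p = 0.614 paired and 0.821 unpaired at 5 CPM, 0.121 unpaired over all genes). With all libraries and that filter, this list too was called higher only when paired over all genes (camera adjusted p = 0.0217, and 0.410 with an estimated correlation). IL2RG fell by 0.44 on the log2 scale, and the kinase gene PIM3 rose by 0.34 (SE 0.083, edgeR adjusted p = 0.0451), with an edgeR adjusted p of 0.117 in the restricted fit.

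Genes that mark stages of NK cell maturation did not move as lists. Of genes of mature CD56-dim NK cells, 1 of 23 rose, 0 fell and 22 did not pass, with 3 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.614 paired and 0.631 unpaired at 5 CPM, 0.197 unpaired over all genes). TBX21, a transcription factor gene of mature NK cells, had a difference of 0.18 (edgeR adjusted p = 0.0741). Of genes of less mature CD56-bright NK cells, 0 of 22 rose, 0 fell and 22 did not pass, with 0 higher and 0 lower adjusted over the list alone (camera adjusted p = 0.613 paired and 0.707 unpaired at 5 CPM, 0.961 unpaired over all genes). Their median and mean were -0.019 and -0.054 while the unpaired camera statistic was on the higher side, and TCF7 had a difference of -0.13 (edgeR adjusted p = 0.327). Of tissue residency and TGF-beta response genes, 0 of 24 rose, 1 fell and 23 did not pass, with 0 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.462 paired and 0.631 unpaired at 5 CPM, 0.893 unpaired over all genes), with a median of 0.034 and a mean of -0.055. ZNF683 was the member that fell, and LDLRAD4 had a difference of -0.24 (edgeR adjusted p = 0.102). Of lymphocyte transcription factors, 1 of 48 rose, 0 fell and 47 did not pass, with 4 higher and 0 lower adjusted over the list alone (camera adjusted p = 0.824 paired and 0.970 unpaired at 5 CPM, 0.0646 unpaired over all genes), the riser being IRF1. Of the other ETS family transcription factors, 0 of 16 rose, 0 fell and 16 did not pass, with 0 higher and 0 lower adjusted over the list alone (camera adjusted p = 0.177 paired and 0.137 unpaired at 5 CPM, 0.814 unpaired over all genes). ERF and ELF2 had differences of -0.22 (edgeR adjusted p = 0.118) and -0.078 (edgeR adjusted p = 0.420).

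Interferon response genes had the highest median of all lists, 0.22 on the log2 scale, and it came from replicate pair 1. The medians in pairs 1, 2 and 3 were 0.50, 0.039 and 0.046. Of its members, 5 of 50 rose, 0 fell and 45 did not pass, with 26 higher and 0 lower adjusted over the list alone (camera adjusted p = 1.31e-10 paired and 2.83e-14 unpaired at 5 CPM, 1.03e-11 unpaired over all genes, and adjusted p = 0.643 with an estimated correlation). Without pair 1 the camera adjusted p was 0.849, against 3.86e-22 and 2.14e-22 without pair 2 or 3. IFIH1, a sensor of viral RNA, rose by 0.28 (SE 0.065, edgeR adjusted p = 0.0365) and GBP5, which encodes a guanylate-binding protein, by 0.16 (SE 0.037, edgeR adjusted p = 0.0410), and ISG15 had a difference of 0.73 (edgeR adjusted p = 0.118). IFIH1 and GBP5 had edgeR adjusted p of 0.106 and 0.125 with the genes of at least 5 CPM fitted alone. Of S phase genes, 1 of 44 rose, 0 fell and 43 did not pass, with 8 higher and 0 lower adjusted over the list alone (camera adjusted p = 0.0155 paired and 0.0176 unpaired at 5 CPM, 0.000538 unpaired over all genes, adjusted p = 0.643 with an estimated correlation and 0.210 without pair 1). MCM6 and MCM7, helicase subunit genes, had differences of 0.15 (edgeR adjusted p = 0.0629) and 0.15 (edgeR adjusted p = 0.0536). Of G2 and M phase genes, 0 of 49 rose, 0 fell and 49 did not pass, with 0 higher and 0 lower adjusted over the list alone (camera adjusted p = 0.867 paired and 0.904 unpaired at 5 CPM, 0.265 unpaired over all genes), and CDC20 had a difference of 0.30 (edgeR adjusted p = 0.0678). Of p53 targets, 1 of 28 rose, 0 fell and 27 did not pass, with 1 higher and 0 lower adjusted over the list alone (camera adjusted p = 0.664 paired and 0.631 unpaired at 5 CPM, 0.211 unpaired over all genes). Of apoptosis regulators, 2 of 30 rose, 1 fell and 27 did not pass, with 2 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.664 paired and 0.738 unpaired at 5 CPM, 0.136 unpaired over all genes). PMAIP1, a member of both lists that encodes a death-promoting protein, rose by 0.26 (SE 0.059, edgeR adjusted p = 0.0332), with an edgeR adjusted p of 0.0832 in the restricted fit, and AEN had a difference of 0.16 (edgeR adjusted p = 0.237).

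Markers of other cell types were at similar levels in both groups, apart from small sets of low counts. T cell markers summed to 404 ± 147 CPM in FLI1 KO and 405 ± 170 CPM in NTC (SD, n = 3), and markers of helper-like innate lymphoid cells to 221 ± 80.1 CPM and 222 ± 74.9 CPM. B cell markers summed to 6.21 ± 1.13 CPM and 6.78 ± 0.446 CPM, and monocyte and myeloid markers to 8.67 ± 6.27 CPM and 6.71 ± 3.44 CPM. These 4 marker lists did not pass the unpaired camera test, with adjusted p of 0.381 for T cell, 0.871 for helper-like, 0.620 for B cell and 0.814 for monocyte markers. T cell markers had a median of -0.00375 and a mean of 0.080, and helper-like markers a median of 0.00125 and a mean of -0.047. The 5 measured markers of erythroid cells and of K562, a leukaemia line used as a feeder for NK cells, summed to 10.3 ± 0.323 CPM in FLI1 KO and 13.0 ± 1.53 CPM in NTC. The 4 measured markers of megakaryocytes and platelets summed to 2.36 ± 0.508 CPM and 3.94 ± 1.18 CPM. Both lists were lower in FLI1 KO in the unpaired camera test (adjusted p = 0.00386 and 0.00326, and adjusted p = 0.298 and 0.298 with an estimated correlation). Of these markers, 1 of 5 and 0 of 4 had at least 5 CPM, and protein-coding genes under 5 CPM had a median log2 difference of -0.20 in the paired fit. No member of any marker list passed the paired edgeR test over all genes, and adjusted over the list alone 1 erythroid and 1 T cell marker were lower there and 1 monocyte marker was higher. That marker, LYZ, had a paired difference of 0.66 (SE 0.18, edgeR adjusted p = 0.0745) and was higher in FLI1 KO in all 3 pairs. Its level was 4.77 ± 4.33 CPM in FLI1 KO and 2.91 ± 2.28 CPM in NTC. Without FLI1 KO replicate 3 its unpaired log2 fold change was -0.24. LYZ and CXCL8, a chemokine gene that monocytes also express, both had their lowest level in replicate 2 and their highest in replicate 3 in each group. In the unpaired edgeR fit 1 erythroid marker was lower adjusted over the list alone.

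FLI1 KO libraries held fewer counts of gene families listed as silent in lymphocytes. After thinning every library to the smallest total, 25898, 26888 and 29068 genes had a count in FLI1 KO replicates 1, 2 and 3, and 32247, 31443 and 40068 in NTC replicates 1, 2 and 3. The 12 families, such as olfactory receptors and keratins, held 732 genes, taken only where their mean was under 2 CPM. Their summed level was 61.5 ± 12.4 CPM in FLI1 KO and 128 ± 75.1 CPM in NTC (SD, n = 3). It was higher in NTC in every pair, by 1.40-fold to 2.85-fold, and reached 215 CPM in NTC replicate 3. Processed pseudogenes of ribosomal protein genes followed the same direction, and 222 of them summed to 296 ± 6.49 CPM in FLI1 KO and 447 ± 15.7 CPM in NTC. Of these, 55 fell and 1 rose in the paired edgeR fit, with a median log2 difference of -0.35 against 0.059 for their 61 parent genes. The 99 protein-coding genes under 5 CPM that fell, PTH1R and ALK among them, had a median absolute log2 difference of 2.49, and the smallest was 0.89. Among low counts the threshold picks large differences. Whether these falls and the lower silent families share a cause was not tested.

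**Figure D3:**
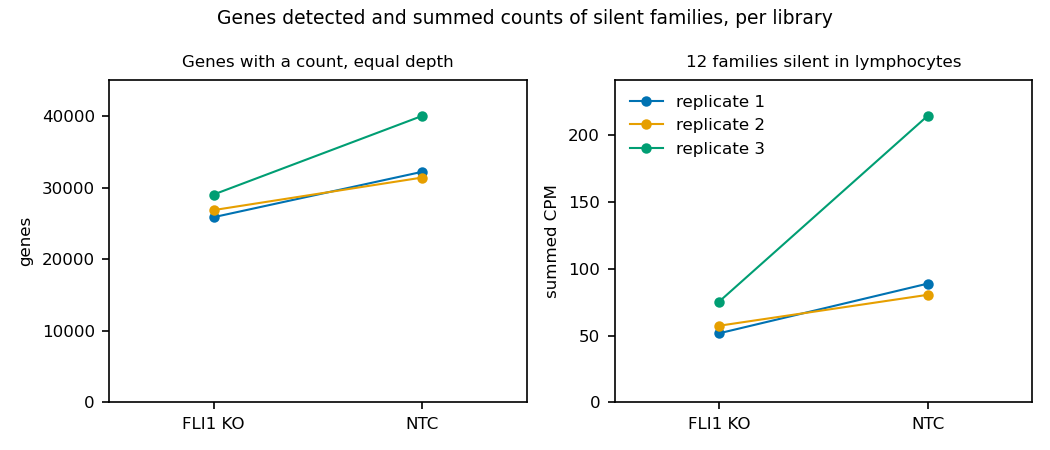
Number of genes with a count after thinning each library to the same total (left) and the summed CPM of 12 gene families silent in lymphocytes (right), with lines joining the FLI1 KO and NTC libraries of each replicate number. Both were higher in NTC in all 3 pairs.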

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

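The alternatives in the paired fit, those restricted to protein-coding genes or genes of at least 5 CPM, and the leaving out of replicate pairs were chosen only after the results were seen. FLI1 stayed lower and short of the threshold under the alternatives of the unpaired fit, with the replicate block and with the block at 5 CPM or more, with log2 differences from -0.15 to -0.077. The unpaired edgeR count of 0 genes (713 at an unadjusted p under 0.05) held with DESeq2 size factors, limma-voom, protein-coding genes only, genes of at least 5 CPM, a 1.5-fold limit and each library left out. It became 246 with no filter (23 higher, 223 lower), 1 with the stricter filter (0 higher, 1 lower), 64 with DESeq2 (0 higher, 64 lower) and 399 with the replicate block (149 higher, 250 lower). The paired count of 399 became 1061 with no filter (507 higher, 554 lower), 198 with the stricter filter (64 and 134), 687 with limma-voom (299 and 388), 89 with genes of at least 5 CPM (21 and 68) and 199 at 1.5-fold or more (4 and 195). DESeq2 with the block gave 85 higher of 266, and protein-coding genes alone 159 lower of 282. With a replicate pair left out the paired count ran from 57 without pair 2 (3 higher, 54 lower) to 867 without pair 3 (426 higher, 441 lower). The filters differ in which low counts are tested and the fold limit removes small changes by construction, and for the other moves the cause was not tested. The unpaired lists, 18 higher and 3 lower, became 35 and 0 with no filter, 10 and 2 with genes of at least 5 CPM, and 0 and 0 with an estimated correlation or fry, unpaired or paired, and at 5 CPM with an estimated correlation. They ran from 10 higher without FLI1 KO replicate 1 to 26, and from 2 to 4 lower, with each library left out. The 15 higher and 2 lower lists of the paired test at 5 CPM became 0 and 0 with an estimated correlation or fry, and ran from 5 higher without pair 1 to 15, with 2 lower each time. The cause was not tested. Of the single values, with each library left out the log2 difference of H2AC21 ran from -0.030 (without FLI1 KO replicate 1) to 0.80, that of H2AC16 from -0.066 (without FLI1 KO replicate 1) to 0.80, that of ZNF683 from -1.22 to 0.14 (without NTC replicate 3, and 0.024 without FLI1 KO replicate 2), that of LYZ from -0.24 (without FLI1 KO replicate 3) to 1.42, and the median of the cytosolic ribosomal proteins from -0.014 (without FLI1 KO replicate 1) to 0.14. Leaving out a single library in the unpaired fit unbalances the replicate numbers between the groups, so the level of each replicate enters these values. The other 1219 values of named genes under alternatives kept their direction and their side of the threshold, and 101 went past it, 61 of these with the replicate block. Of the medians of called lists, 184 kept both and 145 lost the call in the same direction. Of the summed marker levels, 27 moved by less than their SD and 9, all under another filter, by more. In counts drawn from the paired model, the unpaired edgeR fit recovered 0% of simulated 1.25-fold changes in genes of at least 5 CPM and the paired fit 72%. The part of depth in this limit was not tested.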

Other observations

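All tests below were chosen with the patterns already seen, but what each would show was written down before its result was computed, except that a family was left out of the test of transcription, and the bound of 80% for off-target fragments dropped, after their values were seen, and that the ratios with other filters were added later. Counts of families silent in lymphocytes differed between the groups in nearly all families: olfactory receptors summed to 12.4 ± 0.75 CPM in FLI1 KO and 23.7 ± 10.1 CPM in NTC (SD, n = 3), mucins to 6.05 ± 0.712 and 15.5 ± 9.6 CPM and keratins to 5.12 ± 0.661 and 9.30 ± 3.19 CPM, while bitter taste receptors were at 7.87 ± 2.13 and 7.81 ± 0.8 CPM.

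The first pattern is this lower level of silent families in FLI1 KO libraries. A difference in sequencing depth is argued against, since NTC had more genes with a count in 3 of 3 pairs after every library was thinned to the same total. DNA or other off-target fragments in the NTC libraries stay open. That 91.7% of the 12 families were higher in NTC in all pairs does not speak for them, since lower transcription of these genes without FLI1 predicts the same. Lower transcription stays open too, as the largest family difference per kilobase was 3.72 times the smallest, between the bounds of 2 and 4, over the 11 families whose pairs all went one way. With the bitter taste receptors included the family differences ran from -0.00399 to 0.105 CPM per kilobase, beyond the bound of 4 set for lower transcription. NTC was higher in 1 of 3 pairs in that family, so its own difference is not determined. Bitter taste receptors had 7.87 CPM in FLI1 KO over 15.9 kilobases of coding sequence, against 12.4 CPM over 363 kilobases for olfactory receptors. That family may therefore not be silent in these cells.

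The second pattern is the lower level of processed pseudogenes of ribosomal protein genes, 97 of 222 lower in all pairs and 16 higher. The same background as in the silent families may account for part of it, but the ratio of the median differences per kilobase, pseudogenes over silent genes, turned on the filter on low counts. It was 3.26 (95% bootstrap interval 1.95 to 6.01) with the filter on both sets, 222 pseudogenes and 85 silent genes. It was 17.1 (10.97 to 23.80) with these pseudogenes and all 732 silent genes, and 0.786 (0.334 to 1.09) with no filter, over 1524 pseudogenes. The interval lies above the bound of 2 only where the filter picks the pseudogenes by their counts and not the silent genes, so this does not decide. Lengths were of transcripts for pseudogenes and of coding sequence for silent genes. The probe panel of the enrichment is not given, so the same background need not give equal differences per kilobase in both sets. The ratio therefore cannot decide at any filter. Reads of the parent genes assigned at a fixed rate would move pseudogenes and parents alike, and their medians differed by -0.41 on the log2 scale (95% interval -0.55 to -0.25), between the bounds of 0.2 and 0.5 set for it. No value separates these explanations from lower transcription, which was not tested for them.

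The third pattern is the lower calls among short protein-coding transcripts, such as COX8A, RPS29, RPL36 and RPS21. As a class, short transcripts were lower than longer ones by a small amount. In the paired fit over all tested genes the median log2 difference at 5 CPM or more was -0.0096 under 300 bases and 0.015 from 300 to under 600 bases. It was 0.033 from 600 to under 1200 bases, 0.039 from 1200 to under 2400 bases and 0.043 at 2400 bases or more. A trend with coding length and GC content across all genes was removed per library in the paired fit, and 21 of 29 lower calls under 600 bases (72.4%) stayed past the threshold, between the bounds of 50% and 75%. Their median log2 difference went from -0.31 to -0.28, with a median SE of 0.044. Such a trend may therefore account for some of these calls, and for COX8A the difference was -1.08 before and -1.04 after. Whether transcripts of these genes fell in the cells or were recovered less well from short fragments in FLI1 KO libraries was not tested.

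Other splits of the libraries were counted for each result, and they are too few for a share under 0.05. The unpaired edgeR test called 0 genes in the real split and at most 0 in the other splits, 10 splits in all. With the replicate block the real split called 399 genes and the highest other split 0, among 4 splits. The unpaired camera test called 21 lists in the real split and 24 in the highest of the other splits, which puts libraries of the same replicate number in the same group. Among the 4 splits that part every pair, the real value was 21 and the highest other 16. With the block the values were 24 and 21 lists, and at 5 CPM or more 17 and 11.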
